A study of Drosophila melanogaster with 6 samples.

How the data were processed

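Gene expression was measured in Drosophila S2 cells, a cultured line of embryonic origin with features of macrophage-like blood cells. Cells received RNA interference (RNAi) against CP190, against CG9740 or, as the control, against LacZ, a bacterial gene that flies lack. Each of the 3 conditions had 2 arrays, described in the series' design as biological replicates, which makes 6 arrays in all. The labels do not say whether the cultures were grown or processed on separate days. Per the labels' protocols, total RNA was extracted with an organic reagent and a column kit, amplified with a whole transcriptome kit, labelled with biotin and hybridised to 1-colour oligonucleotide arrays.

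The deposited values are log2 probe set levels, 1 per array, and per the submitters' processing notes GCOS and RMA were used to make them. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of each probe set. Because of that step, a shift shared by most transcripts would not be seen, and the differences of low probe sets are compressed toward 0. Software versions and the annotation used by the authors are not given in the sources used here. The scanner files were not used here, so probe-level quality and background could not be examined. Median levels lay between 5.69 and 5.74 on the log2 scale on all 6 arrays.

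Of 18952 probe sets in the table, 183 control probe sets were left out and 18769 were tested, with no filter on dim probe sets. The platform annotation named 1 gene for 13647 of those, several genes for 402 and none for 4720, which are unnamed here rather than without a gene. By Entrez identifier, 13544 of the probe sets with 1 gene matched the gene table of assembly Release 6, and 0 symbols needed an update. That table was used for names and for which genes neighbour each other, and no coordinates are given because the probes carry no genome build. The named probe sets covered 11982 genes. At the gene level, a gene is represented by its brightest probe set over all 6 arrays, and probe sets naming several genes were not used for any gene. Several well-known genes, such as members of the Hsp70 family and part of the Hox complex, are not among the named probe sets and were not analysed here.

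Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without an intensity trend and not robust), in 1 fit over all 6 arrays with the 3 conditions as groups. All adjusted p-values of probe sets are from this limma fit after Benjamini-Hochberg adjustment over the 18769 probe sets, two-sided, with a threshold of 0.05 and no minimum fold. The fit had 3 residual and 5.05 prior degrees of freedom. Values are given as log2 fold change ± SE from the fit, or as a group's mean ± SD with n = 2. With 2 arrays per condition, the number of arrays limits the precision. The p-values measure the spread between these arrays, part of which may be technical.

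A set of 29 gene lists, fixed before the data were examined, covered insulator and chromatin proteins, stress, immunity, cell cycle, metabolism, translation, signalling and markers of other cell types. Each list was tested at the gene level with limma's camera, with a preset inter-gene correlation of 0.01, and adjusted over the 87 tests of 29 lists and 3 comparisons. Camera compares a list with the other genes. It was repeated with a correlation estimated for each list, and fry was run to ask whether the genes of a list move, on balance, one way, or change in either direction. Members past the threshold were counted over all probe sets and also adjusted over the list alone.

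The named genes were set by a rule fixed before the data were examined. It takes both RNAi targets and CG8436. For each comparison against LacZ RNAi it takes up to 10 genes each way with the largest change among those past the threshold whose 2 RNAi arrays lie on the same side of both LacZ arrays, and for CP190 RNAi against CG9740 RNAi up to 5 each way. It adds the genes past the threshold in both comparisons against LacZ RNAi, up to 10 in the same direction and up to 5 in opposite directions. It also adds up to 4 members of each list past the threshold or, where fewer than 2 passed, its 2 brightest members. Where fewer than 10 genes passed, the 5 smallest p-values each way are added, as not past the threshold. The 2 brightest members are printed below for lists that passed camera, and other lists are summarised, which departs from the rule as fixed. Genes named outside the rule are marked as chosen after their values were seen.

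The fit was tested on simulated data with 200 changed probe sets among 18769, with variances drawn from the fitted distribution. For CP190 RNAi against LacZ RNAi it recovered 33.1% of changes of 0.5 on the log2 scale, 94% of changes of 1 and 99.8% of changes of 2, with 5.02% false calls among all calls. For CG9740 RNAi against LacZ RNAi the shares were 28.1%, 94.5% and 99.7%, with 4.77% false calls. Benjamini-Hochberg adjustment is laxer the more probe sets change, so these shares hold for 200 changed ones. They also hold only for changed probe sets drawn at random, without regard to their spread. In the data 41 probe sets differed at least 2-fold from LacZ RNAi in each comparison. Of those, 9 passed the threshold in CP190 RNAi and 6 in CG9740 RNAi. Among the 19 that differed at least 2-fold in both comparisons, the LacZ arrays themselves differed at least 2-fold in 11. An uncalled change of 2-fold is therefore not excluded.

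Both comparisons against LacZ RNAi share the LacZ arrays, so 100 simulations of unchanged groups against shared controls give the overlap, the correlation and the count of shared 2-fold differences that arise with no effect. Alternatives were the threshold, the eBayes settings, filters on dim probe sets, other normalizations of the deposited values, the arrays in the fit, array weights, a replicate block, the gene-level rule and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.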

Results

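Transcript levels of S2 cells were compared between 3 RNAi conditions, CP190, CG9740 and the LacZ control, with 2 arrays each. CP190 is a zinc finger protein of insulator complexes and centrosomes. CG9740 is now named Ibf2 and encodes an insulator binding factor, as does its neighbour CG8436, now named Ibf1. The series title gives the purpose as an analysis of co-regulation by CP190 and CG9740. Replicate arrays correlated across 18769 probe sets at r = 0.9982 in CP190 RNAi, 0.9976 in CG9740 RNAi and 0.9974 in LacZ RNAi. The SD of the difference between the 2 arrays of a condition was 0.167, 0.193 and 0.199 on the log2 scale, in the same order. Probe sets that differed over 2-fold between replicates numbered 3 in CP190 RNAi, 43 in CG9740 RNAi and 52 in LacZ RNAi. As a measure of RNA quality, the 3' minus 5' difference of the 18S ribosomal RNA control was 1.9 on CG9740 RNAi array 2 and between 1.43 and 1.59 on the other arrays, that of the actin control lay between 0.6 and 0.64 on all 6, that of the eIF-4a control between 1.18 and 1.38, and that of the GAPDH control was 0.86 to 0.88 on the replicate 1 arrays and 0.72 to 0.8 on the replicate 2 arrays.

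Each RNAi lowered its own target, and the difference in the transcript of the other target did not pass the threshold. Cp190 had a mean level of 9.72 ± 0.01 (SD, n = 2) in CP190 RNAi, 11.86 ± 0.08 (n = 2) in LacZ RNAi and 11.67 ± 0.18 (n = 2) in CG9740 RNAi. It was 4.42-fold lower in CP190 RNAi than in LacZ RNAi (log2 fold change -2.15 ± 0.11 SE, adjusted p = 0.00068), and its difference in CG9740 RNAi did not pass the threshold (-0.19 ± 0.11, adjusted p = 0.63). The CG9740 RNAi arrays stood at 11.8 and 11.54, both below the LacZ RNAi arrays at 11.81 and 11.92, so a small fall is not excluded. Ibf2 had a mean level of 7.18 ± 0.18 (n = 2) in CG9740 RNAi, 9.47 ± 0.24 (n = 2) in LacZ RNAi and 9.42 ± 0.14 (n = 2) in CP190 RNAi. It was 4.9-fold lower in CG9740 RNAi than in LacZ RNAi (-2.29 ± 0.14, adjusted p = 0.0014), against a difference of -0.05 ± 0.14 in CP190 RNAi (adjusted p = 0.96). Each target is read by 1 probe set. Without CP190 RNAi replicate 1 the Cp190 value was -2.14 with an adjusted p of 0.052.

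**Figure D1:**
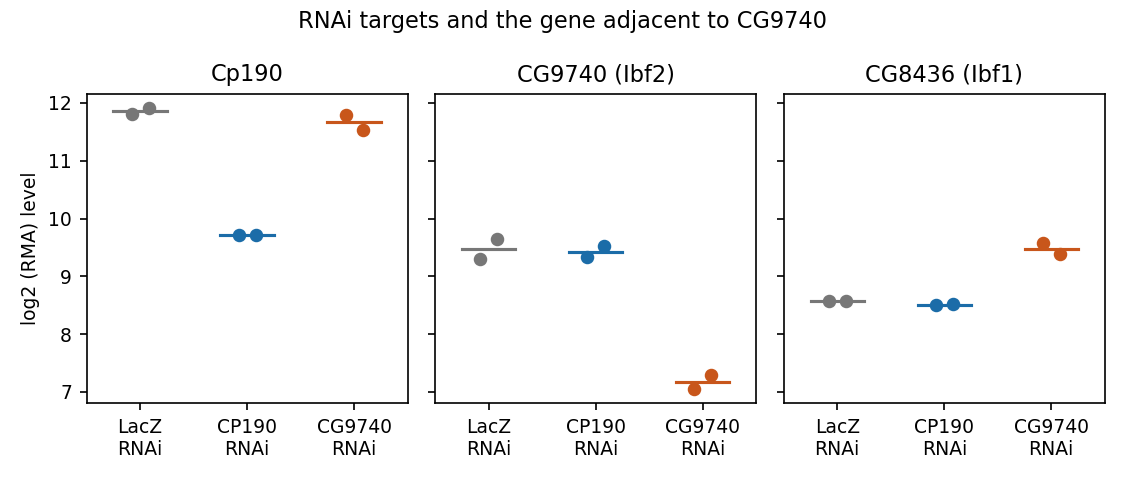
Log2 (RMA) level, on the vertical axis, of Cp190, CG9740 (Ibf2) and CG8436 (Ibf1) on each array of the 3 RNAi conditions; points are arrays and lines are means of 2. Cp190 lies near 9.72 in CP190 RNAi, Ibf2 near 7.18 in CG9740 RNAi, and Ibf1 near 9.48 in CG9740 RNAi against 8.58 in LacZ RNAi.

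RNAi of CP190 changed 13 genes against LacZ RNAi, 5 of them higher and 8 lower, with Cp190 itself among the lower ones. Sid, which encodes a stress-induced DNase, fell by 1.86 on the log2 scale (SE 0.12, 3.63-fold lower, adjusted p = 0.002), from a mean level of 8.41 ± 0.12 (n = 2) in LacZ RNAi to 6.55 ± 0.14 (n = 2). CG10232 was 4.67-fold lower (-2.22 ± 0.18, adjusted p = 0.0075). By the brightest probe set of each gene, the largest rise was that of Asph, an aspartyl beta-hydroxylase, at 2.51-fold (1.33 ± 0.12, adjusted p = 0.013). Next came the intraflagellar transport gene IFT52 at 2.48-fold (1.31 ± 0.12, adjusted p = 0.012) and the nuclear import adaptor Kap-alpha3 at 2.37-fold (1.25 ± 0.1, adjusted p = 0.0075).

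The other genes that fell were CG33307 (-1.33 ± 0.14), CG3703 (-1.17 ± 0.13), the aquaporin gene Prip (-0.99 ± 0.11), the peroxiredoxin gene Prx6c (-0.92 ± 0.1) and yellow (y), a cuticle pigmentation gene (-0.9 ± 0.1), with adjusted p between 0.022 and 0.032. The other genes that rose were CG10508 (0.9 ± 0.11) and DIP-alpha, a cell surface protein of the immunoglobulin superfamily (0.85 ± 0.1), both with an adjusted p of 0.035. Levels of y were low on all arrays, with means of 3.3 ± 0.1 (n = 2) in CP190 RNAi and 4.2 ± 0.15 (n = 2) in LacZ RNAi. For genes with several probe sets the calls did not extend to all of them. A dimmer probe set of Mob2, a kinase cofactor gene, rose 3.73-fold (1.9 ± 0.18, adjusted p = 0.014), while its brightest probe set stood at -0.07 ± 0.16 (adjusted p = 0.94). A further probe set of CG10508 rose (1 ± 0.1, adjusted p = 0.022) and the remaining 1 did not pass (0.53 ± 0.19, adjusted p = 0.55). For Asph and Prip the dimmer probe sets gave 0.36 ± 0.11 (adjusted p = 0.5) and -0.17 ± 0.15 (adjusted p = 0.77).

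At the level of probe sets, 15 passed the threshold in CP190 RNAi against LacZ RNAi, 7 higher and 8 lower, each with an absolute log2 change of at least 0.85. A further view without adjustment gave 1608 probe sets with p under 0.05, where 938 were expected by chance. Without CP190 RNAi replicate 1 no probe set passed in limma (1215 at an unadjusted p under 0.05), without CP190 RNAi replicate 2 it was 2, without LacZ RNAi replicate 2 it was 5, without LacZ RNAi replicate 1 it was 22, and without either array of CG9740 RNAi, which then adds no spread, it was 37.

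Among gene lists, 4 of 29 shifted in CP190 RNAi against LacZ RNAi by camera with the preset correlation. Of 69 measured mitochondrial ribosomal protein genes, 68 had a value above 0 and the median log2 fold change was 0.18 (camera adjusted p = 1.1e-14; adjusted p = 0.84 with an estimated correlation). No single member passed the threshold, over all probe sets or adjusted over the list alone, and 17 were higher at an unadjusted limma p under 0.05. The brightest members, mRpL14 and mRpS5, stood at 0.16 ± 0.09 (adjusted p = 0.66) and 0.01 ± 0.11 (adjusted p = 0.99). Genes of oxidative phosphorylation had a median of 0.11, with 19 of 20 above 0 (camera adjusted p = 0.0047; adjusted p = 0.84 with an estimated correlation). Their 2 brightest members, the ATP synthase genes ATPsynbeta and ATPsyngamma, stood at 0.09 ± 0.09 (adjusted p = 0.81) and 0.11 ± 0.1 (adjusted p = 0.77). No member of this list passed over all probe sets or adjusted over the list alone, and 1 was higher at an unadjusted limma p under 0.05. A trend with gene length or brightness was not checked for this list.

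The list of oxidative and xenobiotic stress genes had a median of 0.1 over 27 members in CP190 RNAi, 21 of them above 0 (camera adjusted p = 0.037; adjusted p = 0.84 with an estimated correlation). Its brightest members were the metallothionein gene MtnA, at -0.4 ± 0.1 (adjusted p = 0.39), and the thioredoxin reductase gene Trxr1, at 0.05 ± 0.08 (adjusted p = 0.9). No member passed the limma threshold over all probe sets or adjusted over the list alone, and 4 were higher and 1 lower at an unadjusted p under 0.05. Genes of lipid and sterol regulation had a median of -0.13 over 18 members (camera adjusted p = 0.018; adjusted p = 0.84 with an estimated correlation). None passed in limma over all probe sets, 1 was lower adjusted over the list alone, namely wun2, a lipid phosphate phosphatase gene at -0.86 ± 0.2 that was named after its value was seen, and at an unadjusted p under 0.05 there were 5 lower and 1 higher. The brightest members were ACC, for acetyl-CoA carboxylase, at -0.15 ± 0.12 (adjusted p = 0.76), and Npc2a, a sterol-binding protein gene, at -0.06 ± 0.08 (adjusted p = 0.88). Without LacZ RNAi replicate 2 the median of the mitochondrial ribosomal protein genes was 0.1, and it was 0.26 without LacZ RNAi replicate 1. The calls of the other 3 lists ended without 1 array. Without LacZ RNAi replicate 2 those of oxidative phosphorylation (median 0.03) and oxidative and xenobiotic stress (0.07) ended. The latter also ended without CP190 RNAi replicate 1 (0.08). Lipid regulation lost its call without CP190 RNAi replicate 2 (-0.05) or LacZ RNAi replicate 1 (-0.09). Without other single arrays the medians went as far as 0.19, 0.21 and -0.19, in the same order of lists.

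The other 25 lists did not pass camera in CP190 RNAi, and their medians lay between -0.16 and 0.07. Among 20 genes of insulator and architectural proteins, with a median of -0.04, 1 fell over all probe sets and adjusted over the list alone, Cp190 itself. The same gene was the 1 that fell among 18 genes of centrosome and microtubule organisation, where the microtubule regulator msps stood at -0.11 ± 0.1 (adjusted p = 0.78). Of the insulator genes, the 2 brightest were Rm62, an RNA helicase gene, at -0.21 ± 0.08 (adjusted p = 0.57), and Cp190. Fry's test for change in either direction passed for both lists (adjusted p = 0.0058 and 0.0064), and both hold the RNAi target.

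RNAi of CG9740 changed 8 genes against LacZ RNAi, 5 of them higher and 3 lower, with Ibf2 among the lower ones. Its neighbour Ibf1 rose 1.88-fold (0.91 ± 0.09, adjusted p = 0.025), from 8.58 ± 0.01 (n = 2) in LacZ RNAi to 9.48 ± 0.13 (n = 2), and stood at -0.07 ± 0.09 in CP190 RNAi (adjusted p = 0.87). Its value lay between 0.82 and 1 with any 1 array left out, and it kept its call only without CG9740 RNAi replicate 1 (adjusted p = 0.045, against 0.069 to 0.26 without any other array and 0.16 with a replicate block). CG10621 rose 3.58-fold (1.84 ± 0.16, adjusted p = 0.0085), CG12477 rose 3.22-fold (1.69 ± 0.09, adjusted p = 0.0014), and eIF4E6, of the cap-binding translation factor family, rose 2.8-fold (1.49 ± 0.09, adjusted p = 0.0014). Kap-alpha3 rose 2.18-fold (1.12 ± 0.1, adjusted p = 0.0088). CG10232 fell by 2.15 (SE 0.18, 4.44-fold lower, adjusted p = 0.0085) and Cyp40, a cyclophilin gene, fell by 0.95 (SE 0.11, 1.93-fold lower, adjusted p = 0.045).

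Genes with the smallest p-values beyond the threshold in CG9740 RNAi included, with values above 0, IFT52 at 0.86 ± 0.12 (adjusted p = 0.13), mlt at 0.95 ± 0.14 (0.19), CG8301 at 0.78 ± 0.12 (0.26), CG34232 at 0.51 ± 0.08 (0.33) and the antimicrobial peptide gene DptB at 0.84 ± 0.14 (0.33). With values below 0 they were CG33307 at -1.04 ± 0.14 (adjusted p = 0.11), the formin gene DAAM at -1.57 ± 0.22 (0.13), Pif1A at -0.51 ± 0.08 (0.31), Cisd2 at -0.52 ± 0.09 (0.38) and the scavenger receptor gene Sr-CIV at -0.5 ± 0.09 (0.41). Each of the 8 called genes had 1 probe set past the threshold, with absolute log2 changes of at least 0.91, and 1612 probe sets had an unadjusted p under 0.05 where 938 were expected by chance. Without CG9740 RNAi replicate 1 the count was 43, without CG9740 RNAi replicate 2 it was 3, without LacZ RNAi replicate 2 it was 4, and without either array of CP190 RNAi it was 5.

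**Figure D2:**
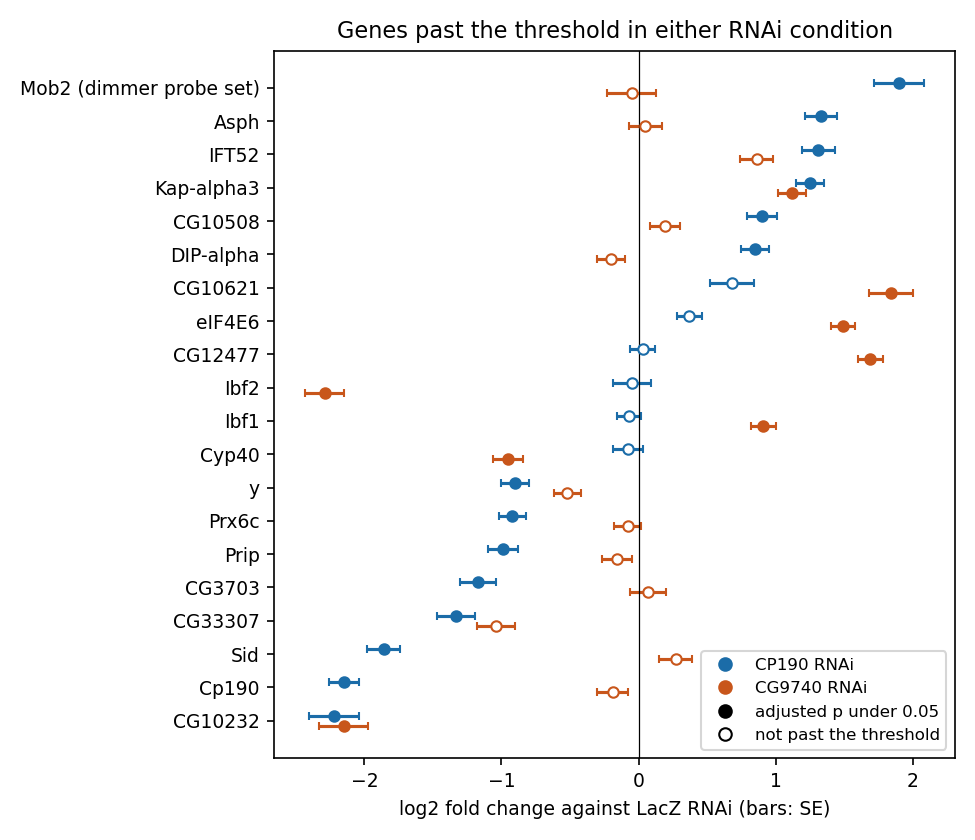
Log2 fold change against LacZ RNAi, on the horizontal axis, of the genes past the threshold in either RNAi condition and of the dimmer probe set of Mob2; bars are SE, filled points have an adjusted p under 0.05. CG10232 and Kap-alpha3 are filled in both conditions, while Ibf1 stands at 0.91 in CG9740 RNAi and at -0.07 in CP190 RNAi.

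In CG9740 RNAi against LacZ RNAi, 6 of the 29 gene lists shifted by camera with the preset correlation. Mitochondrial ribosomal protein genes had a median log2 fold change of 0.22, with 68 of 69 above 0 (camera adjusted p = 3.2e-24; adjusted p = 0.84 with an estimated correlation). No member passed the limma threshold over all probe sets or adjusted over the list alone, and 34 were higher at an unadjusted p under 0.05. The values of mRpL14 and mRpS5 were 0.15 ± 0.09 (adjusted p = 0.63) and 0.14 ± 0.11 (adjusted p = 0.73). Oxidative phosphorylation genes had a median of 0.14, with 19 of 20 above 0 (camera adjusted p = 2.9e-05; adjusted p = 0.84 with an estimated correlation), and ATPsynbeta and ATPsyngamma stood at 0.12 ± 0.09 (adjusted p = 0.71) and 0.15 ± 0.1 (adjusted p = 0.67). No member of this list passed over all probe sets or adjusted over the list alone in limma, and 2 were higher at an unadjusted p under 0.05. Here too a trend with gene length or brightness was not checked. Genes of the RNA interference and small RNA pathway had a median of 0.12, all 13 above 0 (camera adjusted p = 0.018; adjusted p = 0.84 with an estimated correlation). Their brightest members were Dcr-2, the nuclease that processes double-stranded RNA, at 0.19 ± 0.08 (adjusted p = 0.58), and aub, a Piwi family gene, at 0.09 ± 0.08 (adjusted p = 0.78). No member passed in limma over all probe sets or adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. Of the 16 genes fixed for this list, Dcr-1, AGO1 and AGO2 matched no named probe set and are not among the 13.

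The oxidative and xenobiotic stress list had a median of 0.18 in CG9740 RNAi, with 21 of 27 members above 0 (camera adjusted p = 7.5e-05; adjusted p = 0.84 with an estimated correlation). No member passed in limma over all probe sets, and 3 were higher adjusted over the list alone, the glutathione S-transferase genes GstD2 at 1.53 ± 0.39, GstD5 at 1.2 ± 0.23 and GstD3 at 0.76 ± 0.19, with 6 higher at an unadjusted p under 0.05. These 3 were named after their values were seen. MtnA stood at -0.15 ± 0.1 (adjusted p = 0.69) and Trxr1 at 0.02 ± 0.08 (adjusted p = 0.96). GstD2 also differed between replicates, with levels of 7.53 and 8.92 on the CG9740 RNAi arrays and 6.85 and 6.53 on the LacZ RNAi arrays.

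Plasmatocyte markers, genes of macrophage-like blood cells, had a median of -0.15 in CG9740 RNAi, with 3 of 21 above 0 (camera adjusted p = 0.0071; adjusted p = 0.84 with an estimated correlation). No member passed in limma over all probe sets or adjusted over the list alone, and 4 were lower and 1 higher at an unadjusted p under 0.05. Their brightest members were SPARC, a matrix glycoprotein gene, at -0.15 ± 0.12 (adjusted p = 0.72), and the ferritin subunit gene Fer1HCH, at -0.06 ± 0.08 (adjusted p = 0.85). Targets of Wnt, Notch, Hedgehog and EGFR signalling had a median of -0.17, with 2 of 15 above 0 (camera adjusted p = 0.012; adjusted p = 0.84 with an estimated correlation), and 0 passed in limma over all probe sets or adjusted over the list alone, with 4 lower at an unadjusted p under 0.05. The brightest members of the list were kay, which encodes the fly Fos protein, at -0.24 ± 0.11 (adjusted p = 0.59), and the signalling antagonist gene sty, at -0.64 ± 0.25 (adjusted p = 0.58). A dimmer probe set of kay had the opposite sign, at 0.08 ± 0.13 (adjusted p = 0.88).

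Several of these list calls ended when 1 array was left out. Without CG9740 RNAi replicate 2 those of oxidative and xenobiotic stress (median 0.08, against 0.36 without CG9740 RNAi replicate 1) and plasmatocyte markers (-0.08, against -0.24) ended. So did those of signalling targets (-0.11, against -0.21) and the RNA interference list (0.1, against 0.14). The same array had the 18S control difference of 1.9, apart from the other arrays. Without LacZ RNAi replicate 2 the calls of oxidative phosphorylation (median 0.05, against 0.21 without LacZ RNAi replicate 1) and the RNA interference list (0.14) ended. Without LacZ RNAi replicate 1 those of plasmatocyte markers (-0.11) and the RNA interference list (0.12) ended. The RNA interference list thus lost its call with little change of its median. The other 23 lists had medians between -0.1 and 0.05. Among 20 insulator and architectural genes, 1 rose, Ibf1, and 1 fell, Ibf2, over all probe sets and adjusted over the list alone, with a median of -0.1 (camera adjusted p = 0.078). Over all 87 list tests, 16 passed with the preset correlation and 0 with an estimated one, of which 0 had an unadjusted p under 0.05. The median and the mean of a list had opposite signs in 10 of the 87 tests, none of them past the threshold. Fry gave 0 for movement one way (4 at an unadjusted p under 0.05, smallest adjusted p = 0.23) and 5 for change in either direction. Those 5 were the insulator list in every comparison and the centrosome list in both comparisons with CP190 RNAi. Each of them holds a gene that the RNAi targeted, so they cannot tell whether a list changed beyond the targets. In both comparisons with CG9740 RNAi the insulator list also holds Ibf1, which passed the threshold (0.91 ± 0.09 and -0.97 ± 0.09) and was not a target.

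**Figure D3:**
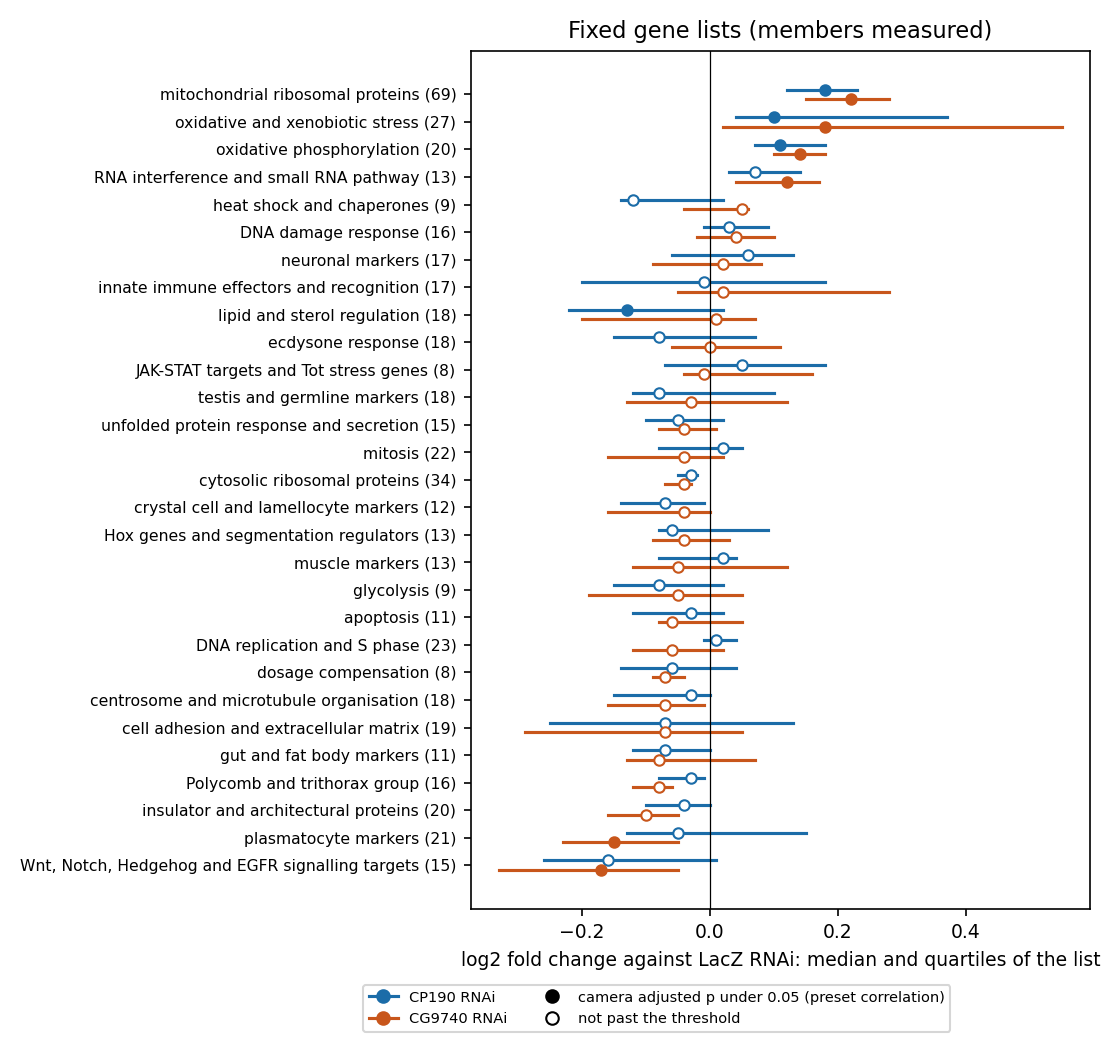
Median (points) and quartiles (lines) of the log2 fold changes against LacZ RNAi, on the horizontal axis, of the members of each of the 29 fixed gene lists; filled points passed camera with the preset correlation, and the number of measured members is in brackets. Mitochondrial ribosomal protein genes have the highest median of the lists in both conditions, 0.18 in CP190 RNAi and 0.22 in CG9740 RNAi.

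The series asks how far CP190 and CG9740 act on the same genes, and 2 genes passed the threshold in both conditions. Kap-alpha3 was higher in both, at 1.25 ± 0.1 in CP190 RNAi and 1.12 ± 0.1 in CG9740 RNAi, with levels of 7.53 ± 0.03 and 7.41 ± 0.02 against 6.29 ± 0.15 in LacZ RNAi (n = 2 each). CG10232 was lower in both, at -2.22 ± 0.18 and -2.15 ± 0.18, with levels of 7.74 ± 0.15 and 7.81 ± 0.07 against 9.96 ± 0.42 in LacZ RNAi (n = 2 each). No probe set passed in opposite directions. Set directly against each other, CP190 RNAi and CG9740 RNAi stood at 0.12 ± 0.1 for Kap-alpha3 and -0.07 ± 0.18 for CG10232. A deviation of the shared LacZ arrays and a response to both RNAi conditions cannot be told apart for these 2 genes.

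Independent lists of these sizes would share 0.0019 higher and 0.0013 lower probe sets, and simulated unchanged groups against shared LacZ arrays shared 0.01 on average and at most 1. Across the 18769 probe sets, which are not independent replicates, the log2 fold changes of both conditions correlated with Pearson's r = 0.68 and Spearman's rho = 0.63, where unchanged groups against shared controls gave a mean r of 0.5 and at most 0.53. The covariance was 0.02 against a simulated 0.0086, a difference of 0.0114. With each condition set against a different LacZ array, r was 0.22 or 0.32 and the covariance 0.0087 or 0.0116. LacZ RNAi has only 2 arrays, and the simulations gave them no wider spread than the others, so part of the excess may come from the shared controls. The count of 2 fell to 0 without CG9740 RNAi replicate 2 or without CP190 RNAi replicate 1. It was 1 without LacZ RNAi replicate 2, where CG10232 stayed, and 1 without CP190 RNAi replicate 2, where both genes lost their call and CG33307 was the shared one. It was 7 without CG9740 RNAi replicate 1 and 4 without LacZ RNAi replicate 1, with both genes among them. With the replicate number as a block it was 0, with unchanged fold changes and adjusted p under 0.1 for both genes. In a fit of CG9740 RNAi and LacZ RNAi alone, without the CP190 RNAi arrays, neither gene kept its call.

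**Figure D4:**
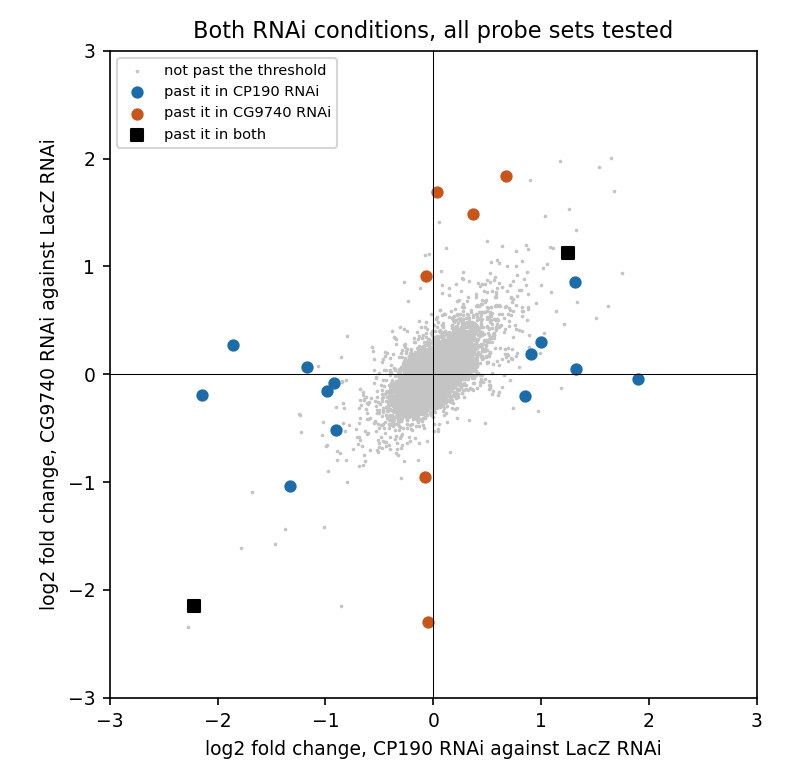
Log2 fold change against LacZ RNAi in CP190 RNAi (horizontal axis) and in CG9740 RNAi (vertical axis); each point is 1 of 18769 probe sets, coloured by the comparison in which its adjusted p was under 0.05. The black squares are Kap-alpha3 (1.25 and 1.12) and CG10232 (-2.22 and -2.15).

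Set directly against each other, CP190 RNAi and CG9740 RNAi differed in 12 genes, 5 higher and 7 lower in CP190 RNAi. Ibf2 was 4.75-fold higher in CP190 RNAi (2.25 ± 0.14, adjusted p = 0.0011) and Cp190 3.87-fold lower (-1.95 ± 0.11, adjusted p = 0.00055). Sid was 4.37-fold lower (-2.13 ± 0.12, adjusted p = 0.00055), CG12477 was 3.15-fold lower (-1.66 ± 0.09, adjusted p = 0.00055), CG3703 was 2.35-fold lower (-1.23 ± 0.13, adjusted p = 0.023) and eIF4E6 was 2.17-fold lower (-1.12 ± 0.09, adjusted p = 0.0079). Ibf1 was 1.96-fold lower (-0.97 ± 0.09, adjusted p = 0.012), so that its level differed between the RNAi conditions as well as from the control.

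Genes higher in CP190 RNAi than in CG9740 RNAi were, besides Ibf2, Asph (1.27 ± 0.12, adjusted p = 0.012), DIP-alpha (1.04 ± 0.1, adjusted p = 0.012), Cyp40 (0.87 ± 0.11, adjusted p = 0.046) and CG6790 (0.77 ± 0.1, adjusted p = 0.046), and Prx6c was the remaining gene that was lower (-0.83 ± 0.1, adjusted p = 0.046). The dimmer probe set of Mob2 was 3.85-fold higher (1.95 ± 0.18, adjusted p = 0.012), and its brightest stood at 0.18 ± 0.16. In all, 15 probe sets passed, 7 higher and 8 lower, and 2 of them had no gene listed. At an unadjusted p under 0.05 there were 871, where 938 were expected by chance. The count was 3 without CP190 RNAi replicate 2, 4 without CP190 RNAi replicate 1 and 6 without CG9740 RNAi replicate 2.

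By camera with the preset correlation, 6 lists differed between CP190 RNAi and CG9740 RNAi, with small medians. DNA replication genes had a median of 0.07 (adjusted p = 0.038) and plasmatocyte markers of 0.12 (0.037), both higher in CP190 RNAi. Heat shock and chaperone genes had a median of -0.07 (adjusted p = 0.03), innate immune genes of -0.09 (0.0092), mitochondrial ribosomal protein genes of -0.05 (0.0071) and oxidative and xenobiotic stress genes of -0.12 (0.037). For all 6 the result was an adjusted p = 0.84 with an estimated correlation. No member of the 6 lists passed in limma over all probe sets. Adjusted over the list alone, the collagen gene vkg was higher (0.88 ± 0.17) among plasmatocyte markers, and DptB (-0.63 ± 0.14) and the peptidoglycan recognition gene PGRP-SC2 (-0.52 ± 0.1) were lower among innate immune genes. Of these 3, vkg and PGRP-SC2 were named after their values were seen. At an unadjusted p under 0.05 there were 0 DNA replication genes, 2 plasmatocyte markers, both higher, 1 heat shock gene, lower, 4 innate immune genes, all lower, 2 oxidative stress genes, both lower, and 1 mitochondrial ribosomal protein gene, which was higher, against the direction of its list. The brightest members of these lists were PCNA at 0.01 ± 0.1 and RfC4 at -0.01 ± 0.09, SPARC at 0.12 ± 0.12 and Fer1HCH at -0.07 ± 0.08, Hsp60A at 0.01 ± 0.08 and Hsc70-4 at -0.03 ± 0.08, Rel at 0.05 ± 0.08 and Dif at -0.02 ± 0.08, mRpL14 at 0 ± 0.09 and mRpS5 at -0.13 ± 0.11, and MtnA at -0.25 ± 0.1 (unadjusted p = 0.039, adjusted p = 1) and Trxr1 at 0.03 ± 0.08. The other 23 lists had medians between -0.07 and 0.08. Without CG9740 RNAi replicate 2, 5 of the 6 calls ended, and the medians of the innate immune and the oxidative stress lists turned to 0.04 and 0.07, while heat shock genes lost their call without CG9740 RNAi replicate 1 (adjusted p = 0.66). Without CP190 RNAi replicate 2, 5 calls ended as well, those of DNA replication (adjusted p = 0.18), plasmatocyte markers (0.32), innate immune (0.062), mitochondrial ribosomal protein (0.055) and oxidative stress genes (0.7). Without CP190 RNAi replicate 1 those of DNA replication (0.087) and heat shock genes (0.25) ended, and DNA replication genes also lost theirs without LacZ RNAi replicate 1 (0.061) or replicate 2 (0.073).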

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

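The block with crossed numbers and the test with separate LacZ arrays were chosen after the results were seen, and the other settings were fixed before the data were examined. The fall of Cp190 and of Ibf2 kept its direction and its side of the threshold under every setting run, except that Cp190 had an adjusted p of 0.052 without CP190 RNAi replicate 1. Leaving out 1 array at a time gave -2.2 to -2.09 for Cp190 and -2.46 to -2.12 for Ibf2. The same series of fits gave 0 to 37 probe sets for CP190 RNAi against LacZ RNAi (15 with all arrays), 3 to 43 for CG9740 RNAi against LacZ RNAi (8) and 3 to 21 for CP190 RNAi against CG9740 RNAi (15), with 0 to 7 shared between both conditions (2) and a correlation of 0.51 to 0.81 (0.68). The lists past the threshold then numbered 2 to 5, 2 to 11 and 1 to 8, and without CG9740 RNAi replicate 2 the medians of the innate immune and oxidative stress lists in CP190 RNAi against CG9740 RNAi turned to 0.04 and 0.07. Over all such fits the medians of these 2 lists ranged from -0.23 to 0.04 and from -0.25 to 0.07. A condition left with 1 array is assumed in these fits to vary like the others.

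Of the counts in CP190 RNAi against LacZ RNAi, CG9740 RNAi against LacZ RNAi and CP190 RNAi against CG9740 RNAi, in that order, a threshold of 0.1 moved the first to 49 and the third to 29, and an intensity trend moved them to 31 and 26. A robust trend gave 53, 13 and 38, with 5 shared. A minimum of 2-fold left 9 in the first, as did the brighter 50% of the probe sets, while the brightest 25% left 3, 1 and 5, with 0 shared. Fewer probe sets and genes enter with these filters. That does not account for every lost call, since DIP-alpha and CG3703 entered the brighter 50% and lost theirs in the first. Fits of only the 2 conditions compared gave 37 and 5 in the comparisons with LacZ RNAi, with 1 shared. The shared one was neither Kap-alpha3 nor CG10232, since both lost their call in the fit of CG9740 RNAi and LacZ RNAi alone. In the brighter 50% of the probe sets, 7 and 10 gene lists passed in the comparisons with LacZ RNAi. With an estimated correlation, or by fry for movement one way, 0 passed in each of the 3 comparisons. By fry for change in either direction 5 passed in all, each holding an RNAi target. The correlation of fold changes was 0.22 or 0.32 with separate LacZ arrays, 0.32 or 0.06 with fully separate arrays and 0.43 over the probe sets past the threshold in either condition. Repeated quantile normalization, median centring, cyclic loess, array weights (0.96 to 1.03) and both gene-level rules kept each count of probe sets within 1.5 times. For the moves without a reason given here, the cause was not tested.

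Whether replicate numbers pair the arrays stays open. Over all probe sets the deviations of same-numbered arrays correlated at -0.191 (CP190 and CG9740 RNAi), 0.155 (CP190 and LacZ RNAi) and -0.315 (CG9740 and LacZ RNAi), while the GAPDH control's 3' minus 5' difference was lower on replicate 2 in all 3 conditions (0.88 and 0.72 in CG9740 RNAi, 0.86 and 0.72 in CP190 RNAi, 0.88 and 0.8 in LacZ RNAi). With a replicate block the counts were 2, 4 and 4, with 0 shared, and 3 gene lists passed in CP190 RNAi against CG9740 RNAi. With the 2 CG9740 RNAi numbers crossed, the block gave 134, 72 and 43. No value could be had from other probe sets of the targets, since each has 1, nor for Ibf2 in the brightest 25%. Signal near background limits the dimmest genes, such as y, whose brightest array stood at 4.3.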

Other observations

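The tests of the shared LacZ arrays, the simulated count of 2-fold differences, and those of Ibf1 against deviating LacZ arrays and against probes that also detect the target, were chosen after the results were seen, as were the genes named in the first paragraphs. The others were written before.

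A set of 19 probe sets differed at least 2-fold from LacZ RNAi in both conditions, 11 higher and 8 lower in both. Simulated unchanged groups against shared LacZ arrays gave 1.38 such probe sets with the same sign on average and at most 5, and 0.03 with opposite signs, so a shared sign is expected from the shared arrays alone. The simulated LacZ arrays had no wider spread than the others, so these counts may be too low. Of the 19, 3 passed the threshold in at least one condition (Kap-alpha3, CG10232 and CG33307) and 16 in neither. The latter include Cyt-b5-r, at 1.68 ± 0.69 (SE) in CP190 RNAi and 1.7 ± 0.69 in CG9740 RNAi, the receptor gene Lgr4, at 1.65 ± 0.6 and 2.01 ± 0.6, the peptidoglycan recognition gene PGRP-SB1, at 1.17 ± 0.63 and 1.98 ± 0.63, and the cytochrome P450 gene Cyp12a4, at 1.05 ± 0.56 and 1.02 ± 0.56. Argk1, for arginine kinase, stood at -1.68 ± 0.27 and -1.09 ± 0.27, and DAAM at -1.47 ± 0.22 and -1.57 ± 0.22. None of these 6 passed the threshold. In 11 of the 19 the 2 LacZ arrays themselves differed at least 2-fold, as for Cyt-b5-r, with 8.02 and 5.89 on the LacZ RNAi arrays and 7.82 and 9.5 on the CG9740 RNAi arrays.

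Among adhesion and matrix genes, Nrg, the fly neuroglian, stood at 0.82 ± 0.12 in CP190 RNAi and 0.4 ± 0.12 in CG9740 RNAi, and the integrin subunit gene Itgbn at -0.69 ± 0.12 and -0.45 ± 0.12, past a threshold adjusted over the list alone and not over all probe sets (adjusted p = 0.075 and 0.58 for Nrg, 0.14 and 0.58 for Itgbn). In CG9740 RNAi the same held for trol, at 1.05 ± 0.28, and Ten-m, at -0.67 ± 0.19 (adjusted p = 0.58 each). The list itself did not pass camera (adjusted p = 0.28 and 0.21). The adjacent collagen IV genes vkg and Col4a1 stood at -0.72 ± 0.17 and -0.96 ± 0.26 in CG9740 RNAi (adjusted p = 0.58 each). Among the 183 control probe sets of the array, 0 passed the threshold adjusted over the controls. The largest rise among them in CG9740 RNAi was that of 1 probe set with levels of 4.21 and 5.35, against 3.48 and 3.1 on the LacZ RNAi arrays (1.49 ± 0.31, adjusted p = 0.12 over the controls).

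Ibf1, the neighbour of the CG9740 target, was higher in CG9740 RNAi with all arrays in the fit (adjusted p = 0.025). With a replicate block the value was the same and the call ended (adjusted p = 0.16), as it did without any 1 array other than CG9740 RNAi replicate 1, where the values stayed between 0.9 and 1. A change of the whole region is argued against by the 3 nearest measured genes on each side (St2, CG16734, CG16736, ATP6AP2, sage and TrpRS), whose median log2 change was 0.03. Deviating LacZ arrays are argued against by the value of -0.07 in CP190 RNAi, which lies within its error of 0, together with the difference between both RNAi conditions (adjusted p = 0.012, and 0.095 with a replicate block). That difference lay between -1.06 and -0.88 with any 1 array left out, though its call did not hold in all of these fits. Probes that also detect the target would give a fall, and Ibf1 stood at 0.91. That value is the observed rise itself, so it is no separate test. A response of Ibf1 to loss of Ibf2 stays a hypothesis from the same data, and an unintended effect of the double-stranded RNA used was not tested.

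Mitochondrial ribosomal protein genes were higher in both conditions by camera with the preset correlation, and not with an estimated one (adjusted p = 0.84 in each), and 0 of the 69 members passed the threshold in either. A trend with gene length and brightness was present and can account for part of the shift, though not for all of it. The list's median lay at percentile 100 of 10000 lists matched on both, in CP190 RNAi (0.18 against a matched median of 0.08) and in CG9740 RNAi (0.22 against 0.1). Over all genes the log2 fold change correlated with gene length at a Spearman's rho of -0.11 and -0.12, in the same order. Variation of the list between arrays stays open. Its median deviation was -0.06 and -0.2 on the LacZ RNAi arrays, 0.05 and 0.04 on those of CP190 RNAi and 0.05 and 0.14 on those of CG9740 RNAi, so that replicates differed by up to 0.15, close to the shift itself. The culture state of single dishes and an effect of either RNAi cannot be told apart with 2 arrays per condition.

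The log2 fold changes of both conditions went together across genes. Noise of the shared LacZ arrays would bring the correlation near 0 once each condition is set against its own LacZ array, and the smaller of those values was 0.22. Since deviations of replicates from different conditions correlated with a size of up to 0.32, noise of the LacZ arrays and a shared response cannot be told apart here. The same holds for the excess of probe sets at an unadjusted limma p under 0.05. They numbered 1608 and 1612 against LacZ RNAi, and 871 between both RNAi conditions, where 938 were expected by chance.

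Whether neighbouring genes changed together was tested on the 200 genes with the smallest p-values. In CP190 RNAi they formed 13 adjacent pairs, against a mean of 2.95 and a 95th percentile of 6 in 10000 shuffles (permutation p = 1e-04, the smallest these shuffles can give), and all 13 pairs moved in the same direction. In CG9740 RNAi they formed 8 pairs, against a mean of 2.96 (permutation p = 0.011), 7 of them in the same direction, and Ibf2 and Ibf1 were among them. The 200 genes that differed most between the 2 LacZ arrays also formed 13 pairs, all 13 in the same direction. An excess of this size thus arises between arrays of 1 condition as well, and what brings the pairs of either RNAi about stays open. In CP190 RNAi the pairs include the run Mrp4, CG6790 and CG5342, at 0.54 ± 0.09, 0.61 ± 0.1 and 0.52 ± 0.09, and the run CG13895, CkIIalpha-i3 and CG13896, at -0.34 ± 0.08, -1.07 ± 0.15 and -0.48 ± 0.09, none of them past the threshold.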
